A study of Mus musculus with 4 samples.

How the data were processed

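Langerhans cells, the antigen-presenting dendritic cells of the epidermis, were compared between mice that lack exon 2 of the aryl hydrocarbon receptor gene (Ahr) and wild-type C57BL/6 mice. Per the labels, ear epidermis was the source, the cells spent 16 hours in culture, and a low-density fraction holding 20 to 35% Langerhans cells was sorted for living MHC class II-positive cells to a purity above 95%. The labels differ on whether whole sheets or a cell suspension were cultured. Per the labels' protocols, total RNA was amplified with a MessageAmp kit, labelled with biotin and hybridised to Affymetrix MOE430A arrays. There were 4 arrays, 2 per genotype. The labels call the samples of a genotype biological replicates, without saying how many mice each came from.

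The deposited values are log2 expression values per probe set, and the submitters' processing notes name affy and RMA, a method that corrects background, normalises arrays by quantiles and summarises the probes of a set. Versions of these tools, the annotation and the probe sequences were not given in the sources used here. The array medians of the deposited log2 values lay between 5.60 and 5.63, and the values were used without further scaling. No pair of arrays held identical values.

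Of 22690 probe sets, 64 Affymetrix controls were left out and 22626 were tested. The platform annotation gave 1 gene symbol to 20380 probe sets, several to 691 and none to 1555. Probe sets with several symbols were tested but not named. Symbols were checked through Entrez identifiers against RefSeq genes of GRCm38.p6, where 20351 probe sets matched and 0 symbols changed. No genome build was named in the sources used here, so that table served only for names and for finding which genes lie near each other. For gene-level results, each of 12393 genes was represented by its probe set with the highest mean over all 4 arrays.

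Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided moderated tests, residual degrees of freedom 2, prior degrees of freedom 2.27). P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets and called at 0.05. All differences are log2, AhR-deficient minus wild-type, with n = 2 arrays per genotype, and SE is limma's moderated standard error. The number of arrays limits the precision, and the median SE was 0.10.

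The design, the alternatives, the named genes and 32 gene lists were fixed before the data were examined. Lists covered the AhR pathway, Nrf2 genes, Langerhans cell identity, dendritic cell maturation, MHC class II and class I presentation, tryptophan catabolism and tolerance, cytokines, uptake receptors, interferon-stimulated genes, NF-kB targets, cell cycle, apoptosis, cholesterol and fatty acid synthesis, lipid handling, glycolysis and hypoxia, the unfolded protein response, actin and adhesion, TGF-beta, the circadian clock, ribosomal proteins, oxidative phosphorylation, the proteasome and immediate early genes. The remaining lists held markers of keratinocytes, T cells, melanocytes, stroma, mast cells, macrophages and neutrophils, B cells, and erythroid cells and platelets. Each list was compared with all other genes by limma's camera with a preset correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation and with fry. Fry asks whether a list moves on balance in a single direction and does not compare it with other genes.

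The rule for named genes took, in each direction, up to 15 genes past the threshold with non-overlapping arrays, filled to 10 by smallest unadjusted p among non-overlapping genes with an absolute log2 difference of at least 1. It also took from each list up to 6 members past the threshold, or the 2 with the smallest p where none passed. Up to 10 genes near Ahr past the threshold, and a fixed set of AhR pathway, costimulation and Langerhans cell genes, were added. Genes within 10 Mb of Ahr were compared with genes elsewhere by Fisher's exact test.

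The steps were tested on 20 simulated sets of 22626 probe sets for this comparison, with 200 probe sets changed in each. At log2 sizes of 1, 2 and 3, the test recovered 48.4%, 89.2% and 95.7% of them, 0 with the wrong sign, and 4.49% of calls were false. A list shifted by 0.5 was found in 100% of sets with the preset correlation and in 0% with an estimated correlation. On average 0.1 unshifted lists were called per set. The simulated genes were independent of each other, so this does not test how the preset correlation behaves when listed genes vary together. Recovery also depends on the 200 changed probe sets, as the adjustment is stricter when fewer probe sets differ. In the data only 4 probe sets passed, so recovery there is likely lower than these shares. The simulation also held no factor shared by arrays of different genotypes.

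Alternatives were a replicate block, eBayes with a trend or robust, leaving out dim probe sets, quantile normalisation again, median centring, array weights, each array left out, other thresholds, 16 added on the linear scale, other choices of probe set per gene, camera on ranks, and windows of 5 and 20 Mb. Bootstrap intervals used 10000 resamples over genes, so they do not measure the spread between arrays. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.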

Results

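The data were expression profiles of Langerhans cells sorted from cultured ear epidermis, with 2 arrays from AhR-deficient and 2 from wild-type C57BL/6 mice. The aryl hydrocarbon receptor is a ligand-activated transcription factor. Across probe sets, the 2 AhR-deficient arrays correlated at r = 0.990 and the 2 wild-type arrays at 0.987, while the pairs across genotypes ranged from 0.979 to 0.989. These correlations are across probe sets, which are not independent replicates. Wild-type replicate 2 was thus closer to AhR-deficient replicate 2 (0.989) than to wild-type replicate 1. AhR-deficient replicate 1 with wild-type replicate 2 (0.9881), and AhR-deficient replicate 2 with wild-type replicate 1 (0.9876), also correlated more highly than the wild-type pair (0.9871).

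The log2 signal of the 3' minus the 5' control probe set for Actb was 2.34 and 2.61 in AhR-deficient cells and 3.16 and 2.65 in wild-type cells. These did not overlap, with the lower values in AhR-deficient cells. For Gapdh it was 2.24 and 2.19 against 2.60 and 1.97, which overlapped. The wild-type replicate 1 array had the largest value for both.

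The signal for Ahr itself was 8.55 and 8.60 in AhR-deficient cells and 7.61 and 8.23 in wild-type cells. The log2 difference of 0.66 (SE 0.23) did not pass in limma (adjusted p = 0.810). The annotation does not place either Ahr probe set in the deleted exon 2, so this gene does not check the genotype labels.

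The comparison of the genotypes asks which transcripts of Langerhans cells differ when AhR is missing. Loss of AhR went with a fall of 4 genes. Ahrr, which encodes the AhR repressor and is a known AhR target, fell by 3.11 on the log2 scale (SE 0.11), from 8.26 and 8.38 in wild-type cells to 5.32 and 5.09. Gpd2, the mitochondrial glycerol-3-phosphate dehydrogenase, fell by 2.62 (SE 0.09). Ier3, an immediate early gene and NF-kB target that lies within 10 Mb of H2-Aa, fell by 2.43 (SE 0.09). Nr4a2, an orphan nuclear receptor of the immediate early class, fell by 2.62 (SE 0.08), from 6.72 and 6.78 to 4.13 and 4.14. These AhR-deficient values lay below the arrays' 25th percentiles of 4.55 and 4.56, so the fall may be understated. The other probe set of Nr4a2 differed by -0.29 (SE 0.08). All 4 had an adjusted p of 0.0403 in limma, and both AhR-deficient arrays lay below both wild-type arrays.

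No probe set passed in the other direction. In limma, 0 probe sets were higher and 4 lower at an adjusted p under 0.05, and 760 were higher and 598 lower at an unadjusted p under 0.05. That is 1358 in total, where chance alone gives about 1131; joining AhR-deficient replicate 1 with wild-type replicate 2 instead gave 1592. Non-overlapping arrays were seen for 35.2% of probe sets, where chance gives 33.3%. With no overlap and a difference of at least 2-fold there were 89 higher and 60 lower probe sets.

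The gene with the greatest difference by the fixed rule was Ido1, the enzyme that starts tryptophan breakdown along the kynurenine route. Its log2 signal was 5.31 and 5.62 in AhR-deficient cells and 8.44 and 8.77 in wild-type cells, a difference of -3.14 (SE 0.17), which did not pass adjustment (limma, adjusted p = 0.104). Probe sets without a single gene symbol lay outside the rule. Among them were larger differences of -3.92 and -3.65, neither past adjustment. Further genes with lower values that did not pass were Ank, a pyrophosphate transporter (-2.52, SE 0.23), Sh3bp5 (-2.18, SE 0.16), Dusp16, a MAP kinase phosphatase (-1.86, SE 0.12), Arrb1, a beta-arrestin (-1.80, SE 0.11), and Hif1a, the oxygen-sensitive transcription factor (-1.02, SE 0.10). Their adjusted p-values in limma ranged from 0.152 to 0.256.

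**Figure D1:**
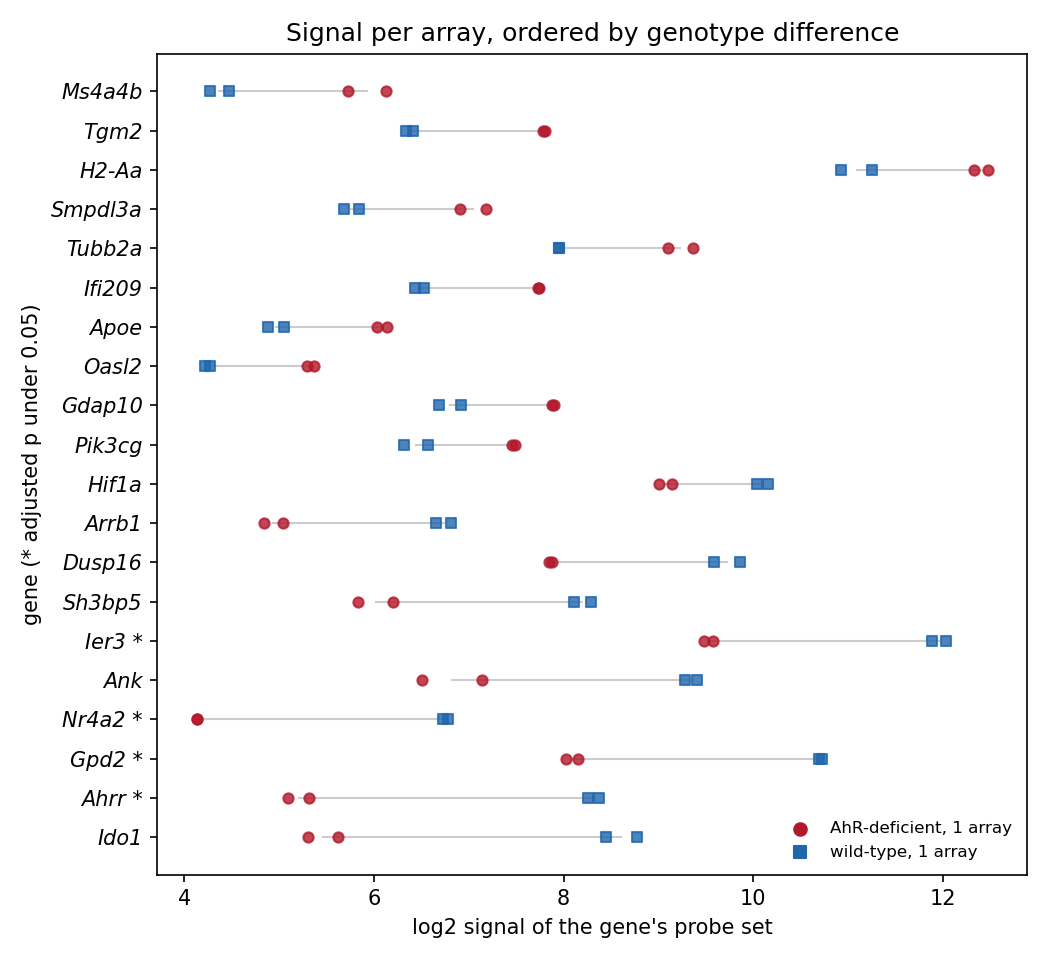
Log2 signal (x axis) of the 20 genes with the clearest genotype differences by the fixed rule (y axis), with 1 point per array, circles for AhR-deficient and squares for wild-type cells, and grey lines joining the group means. The 4 genes marked with a star passed an adjusted p of 0.05; Ahrr lies at 5.32 and 5.09 in AhR-deficient cells and at 8.26 and 8.38 in wild-type cells.

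None of the 10 genes that the rule named as higher passed. Tgm2, a transglutaminase, differed by 1.42 (SE 0.08, limma adjusted p = 0.104), and all 6 of its probe sets were higher in AhR-deficient cells, a pair of them by only 0.05. Ms4a4b differed by 1.56 (SE 0.17), H2-Aa by 1.31 (SE 0.14), Smpdl3a by 1.28 (SE 0.13), Tubb2a by 1.28 (SE 0.12), and Apoe, a lipid carrier, by 1.12 (SE 0.10). The interferon-inducible genes Ifi209 and Oasl2 differed by 1.26 (SE 0.08) and 1.09 (SE 0.08). The last 2 genes of the rule, Gdap10 and Pik3cg, differed by 1.09 (SE 0.11) and 1.03 (SE 0.11), and both lie near Ahr.

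Leaving out any of the 4 arrays ended all 4 calls, with 0 genes called each time. A replicate block and adding 16 on the linear scale also left 0 lower probe sets, and leaving out the dim probe sets left 2 of them, Ahrr and Gpd2, as Nr4a2 was itself among the dim ones and Ier3 had an adjusted p of 0.0520. With a trend in eBayes, Ier3 lost its call (adjusted p = 0.101) while Ido1 (0.0441), Arrb1 (0.0481) and Oasl2 (0.0481) gained one.

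Of the 13 measured AhR pathway and responsive genes, 1 fell, which was Ahrr, and none rose. Classical AhR targets did not pass: the difference was -0.10 (SE 0.09) for Cyp1a1, -0.15 (SE 0.12) for Cyp1b1 and -0.37 (SE 0.12) for Nqo1. Another Cyp1b1 probe set, lower in both AhR-deficient arrays than in both wild-type arrays, differed by -0.52 (SE 0.10). Tiparp, another AhR target, differed by -0.84 (SE 0.40), with -1.48 (SE 0.43) and -0.46 (SE 0.21) for its other probe sets. Its first value rests largely on wild-type replicate 2, with 7.50 and 7.31 in AhR-deficient and 7.67 and 8.81 in wild-type cells. Arnt, the partner of AhR, differed by 0.00 (SE 0.11). As a list these genes were shifted lower (median -0.10, camera adjusted p = 0.0167; adjusted p = 0.486 with an estimated correlation). The mean of -0.33 was drawn lower by Ahrr (-3.11), and the list was not tested without Ahrr. The list's shift did not pass without wild-type replicate 2 (adjusted p = 0.115) or with camera on ranks (0.105). Adjusted over the list alone, 1 gene fell.

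In all, 13 of 32 gene lists were shifted relative to the other genes, 8 higher and 5 lower, in camera with the preset correlation. With an estimated correlation 0 lists passed, and fry also called 0 lists (smallest adjusted p = 0.172). Simulated shifts of 0.5 were never found with an estimated correlation at this number of arrays, so its p-values have little power here. Even so, the estimated correlation was well above the preset 0.01 for some lists. It was 0.43 for MHC class II, 0.58 for MHC class I, 0.65 for glycolysis and hypoxia and 0.28 for oxidative phosphorylation. For cholesterol synthesis it was 0.07 and for interferon-stimulated genes 0.09, also above the preset, and for cell cycle genes -0.01. Where listed genes vary together more than the preset allows, the preset p-values are too small. That does not account for every list. For cell cycle genes the estimate lay below the preset, yet the unadjusted camera p rose from 0.000520 to 0.0568 with it. For AhR pathway genes (estimate -0.02) the unadjusted camera p rose from 0.00628 to 0.102.

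Genes of cholesterol and fatty acid synthesis were higher as a list in AhR-deficient cells (camera adjusted p = 3.85e-13; adjusted p = 0.486 with an estimated correlation). Of 22 measured, 18 had both AhR-deficient arrays above both wild-type arrays and 0 the reverse, with a median of 0.54. No member passed over all probe sets, and 11 rose when adjusted over the list alone. Mvd, a mevalonate pathway enzyme, rose in that test by 0.84 (SE 0.07) and Stard4, a sterol carrier, by 0.63 (SE 0.08).

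Interferon-stimulated genes were also higher as a list (adjusted p = 5.40e-13 in camera; adjusted p = 0.486 with an estimated correlation). Of 25 measured, 18 were higher in both AhR-deficient arrays than in both wild-type arrays and 0 lower, with a median of 0.54, which was 0.33 without wild-type replicate 1 and 0.70 without wild-type replicate 2. None passed over all probe sets, and 8 rose when adjusted over the list alone. They included Oasl2 (1.09), Irf7, a transcription factor of the interferon response (0.75, SE 0.10), and Bst2 (0.99, SE 0.17).

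Antigen presentation genes were higher in cells that had been sorted for MHC class II on their surface. The class II list had a median of 0.93 (camera adjusted p = 1.00e-10; adjusted p = 0.486 with an estimated correlation), with 11 of 15 members higher without overlap and 0 lower. None passed over all probe sets, and 10 rose when adjusted over the list alone. Among these, H2-Aa rose by 1.31 (SE 0.14), H2-Ab1 by 1.24 (SE 0.27) and Cd74, the invariant chain, by 0.93 (SE 0.12). The class I list had a median of 0.48 (camera adjusted p = 7.37e-08; adjusted p = 0.486 with an estimated correlation), which was 0.23 without wild-type replicate 1 and 0.68 without wild-type replicate 2. Of its 14 members, 9 were higher without overlap, and 2 rose when adjusted over the list alone, B2m by 0.67 (SE 0.08) and Psmb9, an immunoproteasome subunit, by 0.71 (SE 0.14).

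**Figure D2:**
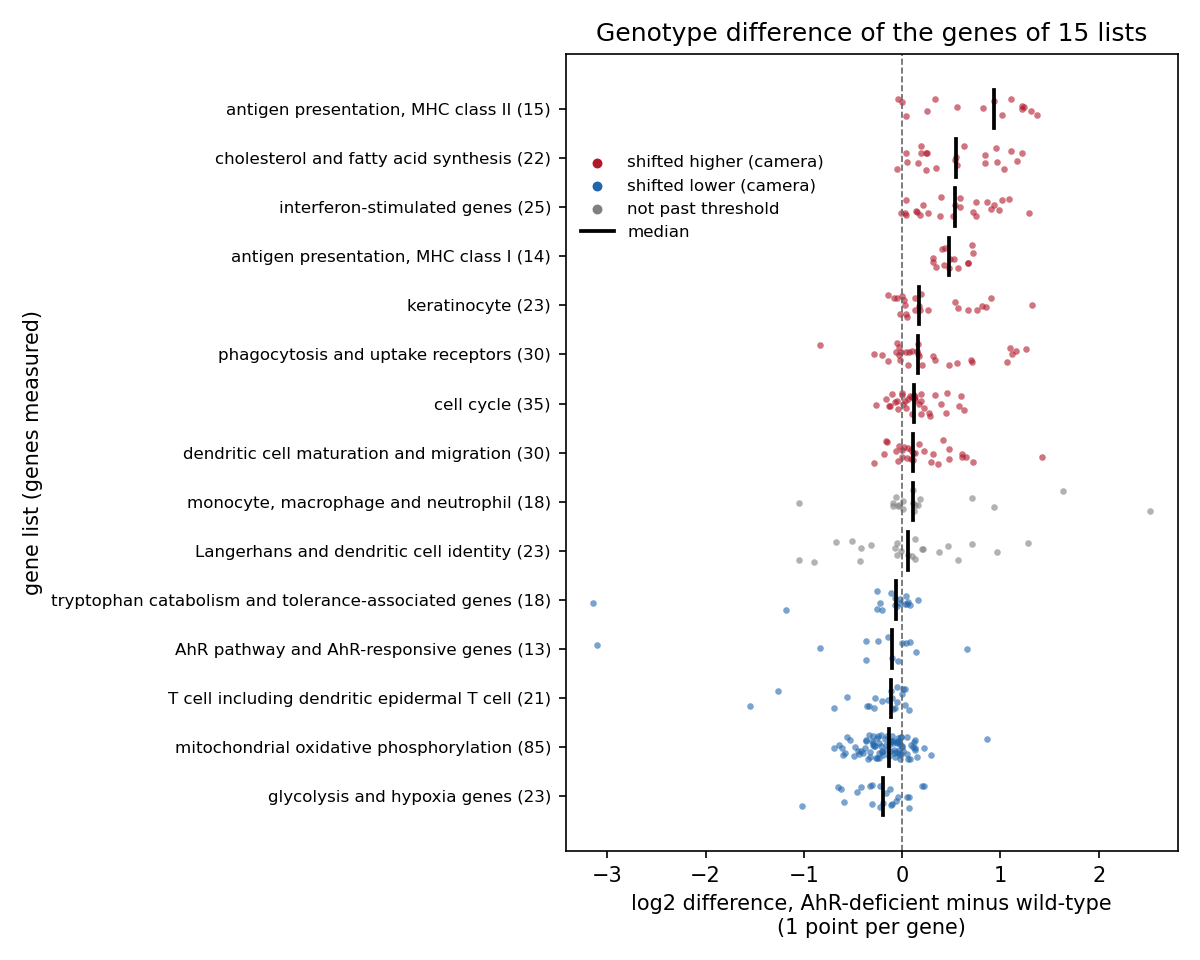
Log2 difference between AhR-deficient and wild-type cells (x axis) for each measured gene of 15 lists (y axis, number of genes measured in brackets), with 1 point per gene and a black line at the list's median. The 13 lists shifted in camera with the preset correlation are coloured, from a median of 0.93 for MHC class II presentation to -0.20 for glycolysis and hypoxia, and 0 of them passed with an estimated correlation.

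Maturation genes of dendritic cells were higher as a list by a small margin (median 0.11, camera adjusted p = 0.00575; adjusted p = 0.486 with an estimated correlation). Of 30 measured, 1 rose when adjusted over the list alone, which was Cd83 (0.61, SE 0.08), a surface marker of mature dendritic cells. The checkpoint ligand Cd274 differed by 1.43 (SE 0.29) and did not pass. The costimulatory genes did not pass either: the difference was -0.16 (SE 0.18) for Cd40, 0.72 (SE 0.41) for Cd80 and 0.22 (SE 0.29) for Cd86, of which another probe set differed by 0.52 (SE 0.09). The migration receptor Ccr7 differed by -0.06 (SE 0.10) and Csf2 by -0.09 (SE 0.08). The shift of this list did not pass without AhR-deficient replicate 1 (median 0.03, adjusted p = 0.170) or without wild-type replicate 2 (adjusted p = 0.0563), and the median was 0.24 without AhR-deficient replicate 2 and 0.22 without wild-type replicate 1.

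Uptake receptors and associated genes were higher as a list (median 0.16, camera adjusted p = 0.00550; adjusted p = 0.486 with an estimated correlation). Of 30 measured, 2 rose and 1 fell when adjusted over the list alone. Cd68, a lysosomal protein of phagocytes, rose by 1.12 (SE 0.19), while Ncf1, a cytosolic subunit of the NADPH oxidase, fell by 0.83 (SE 0.14). This shift did not pass with the dim probe sets left out (adjusted p = 0.135), and the median was 0.04 without AhR-deficient replicate 1 and 0.26 without AhR-deficient replicate 2.

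Cell cycle genes were shifted higher (median 0.12 over 35 genes, camera adjusted p = 0.00278; adjusted p = 0.486 with an estimated correlation), with differences of 0.60 (SE 0.16) for Top2a and 0.46 (SE 0.12) for Birc5. No member passed, over all probe sets or adjusted over the list alone, and the shift did not pass without AhR-deficient replicate 2 (adjusted p = 0.0633).

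Tryptophan catabolism and tolerance-associated genes were shifted lower (median -0.06 over 18 genes, camera adjusted p = 0.0287; adjusted p = 0.486 with an estimated correlation). Adjusted over the list alone, 1 member fell, which was Ido1. The list's mean of -0.29 was drawn lower by Ido1 (-3.14) and Ptgs2, and the list was not tested without them. Ptgs2, an inducible prostaglandin synthase, differed by -1.19 (SE 0.36), with uneven values of 4.923 and 5.848 in AhR-deficient and 6.805 and 6.337 in wild-type cells. The shift did not pass without AhR-deficient replicate 1 (adjusted p = 0.0850), without wild-type replicate 1 (0.276), with camera on ranks (0.105) or with probe sets ending in _s_at or _x_at left out (0.0557). The median was -0.03 without either AhR-deficient replicate, -0.003 without wild-type replicate 1 and -0.11 without wild-type replicate 2.

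Glycolysis and hypoxia genes (median -0.20 over 23 genes, camera adjusted p = 0.00885; adjusted p = 0.683 with an estimated correlation) and oxidative phosphorylation genes (median -0.14 over 85 genes, camera adjusted p = 0.00610; adjusted p = 0.683 with an estimated correlation) were shifted lower. Adjusted over the list alone, Hif1a fell by 1.02 (SE 0.10) among the glycolysis and hypoxia genes. Pfkp, a phosphofructokinase, differed by -0.59 (SE 0.15). In the oxidative phosphorylation list 0 members passed, and its genes with the smallest p went opposite ways, Cox7c with 0.86 (SE 0.25) and Ndufv2 with -0.49 (SE 0.16). Both shifts turned in direction without wild-type replicate 1, where the adjusted p was 0.0363 for the first list and 0.514 for the other. The second also turned without AhR-deficient replicate 1 (0.960), and the first did not pass without AhR-deficient replicate 2 (0.0689). The median of the first was -0.30 without AhR-deficient replicate 1, 0.17 without wild-type replicate 1 and -0.52 without wild-type replicate 2. That of the second was 0.04 and -0.32 without AhR-deficient replicates 1 and 2, and 0.08 and -0.38 without wild-type replicates 1 and 2.

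Markers of Langerhans and dendritic cell identity were not shifted in a single direction (23 genes, median 0.06, camera adjusted p = 0.877). Members moved both ways, with 6 higher and 6 lower without overlap. At an unadjusted p under 0.05 in limma, 3 were higher and 4 lower. The median was -0.02 without AhR-deficient replicate 1 or without wild-type replicate 1, 0.20 without AhR-deficient replicate 2 and 0.13 without wild-type replicate 2. Cd207, the Langerhans cell lectin langerin, differed by -0.07 (SE 0.41) and Epcam by -0.32 (SE 0.19). The values of Csf1r (-1.05, SE 0.26), Cd24a (-0.43, SE 0.09), Tgfbr2 (-0.68, SE 0.17) and Itgax (0.14, SE 0.10) did not pass, over all probe sets or adjusted over the list alone.

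Markers of other cell types moved with genotype, beside the gene groups above. T cell markers were shifted lower (21 genes, median -0.11, camera adjusted p = 1.61e-05; adjusted p = 0.486 with an estimated correlation), and 2 fell when adjusted over the list alone, Cd3g by 1.26 (SE 0.15) and Cd2 by 0.70 (SE 0.12). Of the 21 genes, 9 were lower and 1 higher without overlap. The median was -0.18 without AhR-deficient replicate 2 and -0.21 without wild-type replicate 2. Keratinocyte markers were shifted higher (23 genes, median 0.18, camera adjusted p = 0.00550; adjusted p = 0.486 with an estimated correlation), with Dsp at 6.60 and 5.45 in AhR-deficient and 4.47 and 4.93 in wild-type cells, and Krt14 at 5.55 and 4.96 against 4.60 and 4.76. No keratinocyte marker passed, and this shift was lost without wild-type replicate 2 (median 0.10, adjusted p = 0.0563) and had a median of 0.10 without AhR-deficient replicate 1. Monocyte, macrophage and neutrophil markers were not shifted (18 genes, median 0.11, camera adjusted p = 0.113), although without AhR-deficient replicate 1 (0.0317) and with the dim probe sets left out (0.0425) they passed. Their median was 0.05 without AhR-deficient replicate 1, 0.04 without AhR-deficient replicate 2 and 0.06 without wild-type replicate 1. In that list, the lysozyme gene Lyz1, whose transcript is nearly identical to that of Lyz2, was 7.60 and 6.37 against 4.31 and 4.62, and the chemokine gene Pf4 was 7.26 and 6.41 against 4.98 and 5.41.

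The other lists did not pass in camera. The adjusted p was 0.116 for melanocyte markers, 0.144 for lipid handling and for proteasome subunits, 0.152 for cytokines and chemokines, 0.237 for the TGF-beta pathway, 0.282 for NF-kB targets and 0.320 for the unfolded protein response. It was 0.413 for immediate early genes, 0.452 for stromal markers, 0.478 for the circadian clock, 0.499 for erythroid and platelet markers and 0.509 for mast cell markers. Ribosomal proteins had 0.723, apoptosis genes 0.777, actin and adhesion genes 0.840, and B cell markers and Nrf2 genes 0.849 each. Some of these passed with an array left out: proteasome subunits (8.68e-06) and ribosomal proteins (0.00842) without wild-type replicate 1, and ribosomal proteins (0.00484) without AhR-deficient replicate 1. Lipid handling (0.0188) and immediate early genes (0.0274) passed without wild-type replicate 2, and lipid handling (0.0118) and melanocyte markers (0.0420) without AhR-deficient replicate 2. In 6 lists that did not pass, the Langerhans cell list among them, the median, the mean and the direction of the test differed in sign. Among members of these lists, Nfe2l2, which encodes Nrf2, fell by 1.03 (SE 0.16), Kit fell by 0.64 (SE 0.12) among melanocyte markers, and Apoe rose by 1.12 (SE 0.10), each adjusted over the list alone. Il1b, a cytokine of inflammation, differed by 1.19 (SE 0.28) and did not pass.

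The other probe sets of Pfkp (0.08), Top2a (-0.02), Cd40 (0.06) and Tgfbr2 (0.04 and 0.07) differed in the opposite direction, none at an unadjusted p under 0.05. Those of Hif1a differed by -0.66 (SE 0.15), -0.01 and 0.005, and those of Dsp by 1.14 (SE 0.45) and -0.04. Other probe sets differed more for Cd24a (-0.72, SE 0.22, and -0.71, SE 0.10), H2-Aa (1.99, SE 0.17) and Ifi209 (1.65, SE 0.21). Another probe set differed less for Mvd (0.18), Lyz1 (0.08), Ms4a4b (0.06), Tubb2a (0.36), Pik3cg (0.47), Ahr (0.11), Kit (-0.09), Ptgs2 (-0.16), Ncf1 (-0.29) and Ndufv2 (-0.17). For Oasl2 and Ms4a4b both wild-type arrays, and for Cd3g and Cd2 both AhR-deficient arrays, lay below the arrays' 25th percentiles, so their differences may be understated.

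A targeted gene can carry neighbouring DNA of the strain it was made in, so genes near Ahr were compared with the rest. Of 47 genes within 10 Mb of Ahr, 0 were called in limma, against 4 of 12322 elsewhere (Fisher's exact test, two-sided p = 1). At an unadjusted p under 0.01, 4 of the 47 differed, against 222 elsewhere (Fisher's exact test, two-sided p = 0.0105). The 4, named after their values were seen except for Gdap10 and Pik3cg, were all higher in AhR-deficient cells: Gdap10 by 1.09, Pik3cg by 1.03, Nampt by 0.61 (SE 0.10) and Stxbp6 by 0.60 (SE 0.08). In windows of 5 and 20 Mb, 3 of 31 and 5 of 89 genes differed (Fisher's exact p = 0.0186 and 0.0234). No whole chromosome held more genes at an unadjusted p under 0.01 than the rest after adjustment (Fisher's exact test, smallest adjusted p = 0.717).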

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

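The replicate numbers do not pair the arrays: deviations of same-numbered arrays from their genotype means correlated at -0.309 across probe sets. The deviations of the 2 arrays of a genotype mirror each other, so both pairs give this same correlation. Its negative sign means that AhR-deficient replicate 1 tended to deviate like wild-type replicate 2, and AhR-deficient replicate 2 like wild-type replicate 1. With a replicate block 0 probe sets were higher and 0 lower, and 0 genes were called. The replicate block changed no list shift. Calls adjusted over a list alone and the counts near Ahr were not run with it. The crossed pairing, chosen after seeing the data, also gave 0 and 0 probe sets, and the lists were not run with it. Whether list shifts hold against a factor shared within the crossed pairs was thus not tested. For 4 lower probe sets in the fit as designed, a trend gave 7, leaving out dim probe sets 2, adding 16 on the linear scale 0, an unadjusted p under 0.01 with an absolute log2 difference of at least 1 gave 41, and leaving out an array 0 to 0. For 0 higher ones, the trend gave 1 and the unadjusted threshold 46. Genes called numbered 2 without dim probe sets and 0 to 0 with an array left out. A lone array is then assumed to vary like the other genotype, on 1 residual degree of freedom fewer, so the loss of calls there does not show instability. Quantile normalisation again, median centring, array weights and robust eBayes kept the 4 called probe sets. Ahrr, Gpd2, Nr4a2, Ier3 and Ido1 were lower in every setting run on them, Gpd2 between -2.68 and -2.56.

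Gene lists shifted numbered 0 with an estimated correlation and 0 by fry; other settings gave 11 to 13. With an array left out, the medians of all shifted lists except glycolysis and hypoxia and oxidative phosphorylation kept their sign in all 4 fits. Without wild-type replicate 1, glycolysis and hypoxia genes turned higher (adjusted p = 0.0363) and oxidative phosphorylation genes turned too (0.514), as they did without AhR-deficient replicate 1 (0.960); the cause was not tested. Over the 4 fits with an array left out, the adjusted p ran from 5.09e-14 to 0.0689 for the glycolysis list and from 1.76e-09 to 0.960 for the oxidative phosphorylation list. A list that passed in neither setting was given no direction. Among named genes with differences near 0, leaving out an array turned the sign: Arnt ran from -0.12 to 0.12, Ccr7 from -0.15 to 0.025, Cd207 from -0.60 to 0.46, Cd40 from -0.39 to 0.065 and Cd86 from -0.15 to 0.59. Near Ahr, an unadjusted p under 0.01 gave 3, 4 and 5 genes in the windows of 5, 10 and 20 Mb. Robust eBayes was not run for lists, since camera takes no such option.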

Other observations

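The tests of explanations in this part were chosen after the results were seen, except the comparison of genes near Ahr, which was planned but whose reading was set down afterwards; the limma calls and the camera and fry tests of lists were planned. The genes in this and the next paragraph were picked after their values were seen, and none passed adjustment. Single genes with higher values in AhR-deficient cells were Rtp4, which differed by 2.05, Gbp7 by 1.63, Cyba by 1.16, Irgm1 by 0.75, and the 2 probe sets of Mndal, a neighbour of Ifi209 in the same gene family, by 1.66 and 1.53. Fdps and Sc5d, enzymes of sterol synthesis, differed by 1.22 and 1.04.

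Single genes with lower values in AhR-deficient cells were Ncf4 (-2.52), Ddit4, a stress-induced inhibitor of mTOR signalling (-2.16), Gpc1 (-2.11), and Pla2g7 (-2.04).

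Antigen presentation genes were higher in AhR-deficient cells, with a class II median of 0.93 (camera adjusted p = 1.00e-10; adjusted p = 0.486 with an estimated correlation and 0.210 by fry). More Langerhans cells in these sorts would raise identity genes as much only where their signal comes from these cells and rises in proportion. That was not checked, and the class II list was taken as yardstick after its values were seen. The identity list had a median of 0.055 (bootstrap interval -0.07 to 0.20), lower than the class II median by 0.88 (0.20 to 1.27). Its members moved both ways, with 6 higher and 6 lower without overlap. The identity median was -0.02 without AhR-deficient replicate 1 or wild-type replicate 1, 0.20 without AhR-deficient replicate 2 and 0.13 without wild-type replicate 2. The lowest class II median with an array left out was 0.69. These values do not exclude a higher share. A sort purity above 95% in both genotypes leaves little room for it, where that purity refers to Langerhans cells. DNA of another strain at the H2 complex would not directly reach the 16 members outside chromosome 17, whose median was 0.61 (0.42 to 0.93). With an array left out that median ran from 0.42 to 0.74. An indirect effect of such DNA on genes elsewhere was not tested. For the 13 members on chromosome 17 the strain explanation stays open. Of 271 other genes within 10 Mb of H2-Aa, 3 differed at an unadjusted p under 0.01, against 213 of 12056 elsewhere. The odds ratio was 0.62 (0.13 to 1.86, Fisher's exact p = 0.636), an interval too wide to decide. The 3 were the called gene Ier3 (-2.43), Pla2g7 (-2.04) and Ppp1r18 (-0.47), for which the strain explanation stays open too. More macrophages may contribute and cannot be told apart here. The median of 16 macrophage markers, a list not among the 32 fixed ones, was 0.37 (0.09 to 0.93). Its distance from the class II median ran from -0.36 to 1.05. The fixed monocyte, macrophage and neutrophil list had a median of 0.11 and did not pass (camera adjusted p = 0.113). At an unadjusted p under 0.05 in limma, 6 of the 16 markers were higher and 1 lower. Those higher were Pf4 (1.64), C1qb (1.16), C1qa (1.10), C1qc (0.70), Marco (0.56) and Cd68, at 8.53 and 8.34 against 7.08 and 7.55. The lower marker was Csf1r (-1.05), which is also in the identity list. Of the 16 markers, 9 are in the uptake list and 1 in the identity list, and the MHC class II gate would keep such cells. A comparison of the macrophage interval with the class II median taken as exact had counted against macrophages, and was replaced after it was seen because it left out that median's own spread; a direct effect of AhR on these genes stays open and untested.

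Genes beside Ahr differed more often than others at an unadjusted p under 0.01, 4 of 47 against 222 of 12322 (Fisher's exact p = 0.0105). This is consistent with DNA of another strain kept around the targeted gene, a hypothesis, as the strain in which the allele was made is not given in the sources used here. The comparison rests on 4 genes, all higher in AhR-deficient cells. Fisher's test treats neighbouring genes as independent, which was not checked, so its p-value may be too small. The 47 genes include Ahr itself. A test that read their direction as evidence on probe binding was dropped after it was seen, because it assumed which strain the probes match. Probe sequences were not analysed here, so a strain difference in probe binding, and an effect of AhR on these genes, both stay open.

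The 4 called genes, Ahrr, Gpd2, Nr4a2 and Ier3, fell by at least 2.43 on the log2 scale. Fewer T cells in the AhR-deficient sorts cannot be told apart. Sorting for MHC class II to a purity above 95% would remove most T cells, and the T cell list had a median of only -0.11 (bootstrap interval -0.28 to -0.06). Zap70 (0.03), Cd3e (-0.07), Ctsw (0.07) and Il2rb (0.00) hardly differed, but the signal of those probes may not come from T cells. Of 21 T cell markers, 9 were lower and 1 higher without overlap. At an unadjusted p under 0.05 in limma, 7 were lower and 0 higher. Those lower included Cd3d (-0.56), Cd7 (-0.36), Itgae (-0.34) and Klrk1 (-0.28), so fewer T cells stays open. In addition, Cd3g lay at 4.51 and 4.26 in AhR-deficient cells, where little further fall could be seen. Klrd1 also differed by -1.55 (confidence interval -2.84 to -0.26). The size of that difference rests largely on wild-type replicate 1, with 6.29 and 5.82 in AhR-deficient and 8.25 and 6.96 in wild-type cells. A rule that set the levels of Gpd2 and Ier3 against those of T cell markers had counted against T cells. It was dropped after it was seen because levels of different probes are not comparable. With 4 arrays there are 3 splits into pairs, too few for a share under 0.05; the real split called 4 probe sets and 1 of the 3 splits gave as many, while the highest other gave 0. At an unadjusted p under 0.01 the real split gave 347 probe sets and the split joining AhR-deficient replicate 1 with wild-type replicate 2 gave 459.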
